A study of Mus musculus with 24 samples.

How the data were processed

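RNA was sequenced from the aortas of 24 mice, 1 library per mouse, in 8 groups of 3 mice each: wildtype (WT) or Ppp3cb knockout (KO), control or angiotensin II (AngII), female or male. Ppp3cb encodes the beta isoform of the catalytic subunit of calcineurin, a phosphatase switched on by calcium and calmodulin. The mice were 5 months old, and the treated ones carried osmotic pumps that released AngII at 500 ng per kg per min for 4 weeks. The labels do not say whether control mice carried a pump. Per the labels, total RNA was extracted with TRIzol, treated with DNase, depleted of ribosomal RNA, fragmented and made into indexed Illumina libraries.

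The deposited table holds raw counts per gene, which the authors made without normalization. Their notes name cutadapt 1.8.1, TopHat2 2.0.14, Bowtie2 2.2.5, featureCounts 1.4.6 and the mouse genome build mm10, without settings or strandedness. Every column of the table was a whole-number count and was assigned to its mouse through the sample titles and the column names in the labels. The table lists 41128 genes. All 6021 genes on chromosomes 9, X, Y and MT, and all 526 genes of chromosome 8 that start after position 97565603, have 0 counts in every library. These regions hold 2693 of the 22026 protein-coding genes listed and were treated as not measured. The sexes given in the titles therefore could not be checked on Xist or the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y. Gene names and coordinates came from GENCODE M21 (mm10), which matched 40254 of the 41128 identifiers, and 9 of these lie on another chromosome there. At 9 near-identical snRNA copies the totals were 569085 to 569538, so reads that match several copies appear to have been counted at each of them.

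Library totals were 1523328 to 6352365 counts (median 3835993). Counts on rRNA, snRNA and misc_RNA genes made up 2.508% to 40.28% of a library, so the depth on messenger RNA was lower than the totals. No 2 libraries of a group were copies of one another: the chi-square per degree of freedom between libraries of a group was 6.725 to 103.4. Replicate numbers were taken as labels only, and no block was used.

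Differential expression was tested with edgeR 4.0.16 in R 4.3.3 with limma 3.58.1. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 16316 genes, 13427 of them protein-coding. Library sizes were scaled by TMM factors, and 1 quasi-likelihood model with a coefficient for each of the 8 groups was fitted to all 24 libraries. Each comparison was a contrast of these coefficients, tested two-sided with the quasi-likelihood F-test, and p-values were adjusted by Benjamini and Hochberg over the 16316 genes. A gene was called at an adjusted p under 0.05. Contrasts over both sexes are the mean of the female and the male contrast. Changes are on the log2 scale with their standard error (SE), and levels are in CPM, counts scaled to one library size after TMM, with their standard deviation (SD). A prior count of 2 was used for log2 CPM. Intervals and errors of this kind cover the spread between mice; PCR copies of a molecule were not marked in the reads.

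Fixed gene lists were tested with camera, two-sided, at a preset correlation between genes of 0.01 and adjusted over the 33 lists within a comparison, and again with the correlation estimated from the residuals. The lists covered smooth muscle contraction, extracellular matrix, collagen processing, matrix proteases, TGF-beta, calcineurin and NFAT, the renin-angiotensin-aldosterone system, vascular tone, NADPH oxidase and antioxidants, inflammatory cytokines, interferon response, immediate early genes, the circadian clock, cell cycle, unfolded protein response, oxidative phosphorylation, fatty acid metabolism, heat shock and calcification. Marker lists covered macrophages, lymphocytes, thymocytes, neutrophils and mast cells, endothelium, fibroblasts, adipocytes, brown adipocytes, skeletal muscle, cardiac muscle, neural and Schwann cells, mesothelium and epithelium, blood, liver and plasma proteins, and ribosomal, mitochondrial and unprocessed RNA. The liver list had 1 member past the count filter, Serpina1a, and was not tested. All genes on MT had 0 counts, so none of them was tested in the list of ribosomal, mitochondrial and unprocessed RNA. Members called over all 16316 genes are counted beside those called when adjusted over the list alone.

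Named genes were chosen by a rule. In each of the 5 comparisons over both sexes they were the 10 largest rises and the 10 largest falls among called genes with a mean of at least 1 log2 CPM and the same sign in both sexes. Genes with only a systematic name and pseudogenes were counted but not named. In the other comparisons up to 5 rises and 5 falls were taken. Where no gene was called, the 5 smallest p-values are given as values. Up to 4 members of each list that passed, the calcineurin genes Ppp3cb, Ppp3ca, Ppp3cc, Ppp3r1, Rcan1 and Rcan2, and called genes within 10 Mb of Ppp3cb were also eligible. The groups, the model, the lists, this rule and the first set of alternatives were fixed before the data were examined.

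The procedure was tested on simulated negative binomial counts with the libraries' sizes and the genes' own means and dispersions, in which 100 genes were changed 2-fold and 100 were changed 4-fold among 16316, each gene drawn independently. For AngII in WT it called 31 of the 100 genes changed 2-fold and 71 of the 100 changed 4-fold, with 6 false calls among 16116 unchanged genes. For the interaction it called 5 and 49, and for AngII in WT females 5 and 40. A list of 20 genes changed 1.5-fold was called in each of the 5 comparisons over both sexes, and 0 of 32 random lists were. As the simulated genes did not vary together, this does not show how the preset correlation serves lists of genes that do.

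Alternatives fixed at the outset were RLE size factors, library totals alone, no count filter, a filter of 50 counts in 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom with quality weights, a fit on only the groups in the contrast, the replicate number as a block, adipocyte and skeletal muscle covariates, the estimated correlation for lists, and leaving out each library in turn. Chosen after seeing the data were a fit on protein-coding genes, the share of counts on olfactory and vomeronasal receptor genes as a covariate, a fit without KO control female libraries 1 and 3, a GC content correction, and fits on males or females alone. Single values were compared by exact permutation within strata of sex and treatment or, for 12 against 12 mice, by 100000 permutations. Python 3.11.15 and matplotlib 3.10.9 drew the plots.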

Results

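Gene expression was measured by total RNA sequencing in 24 mouse aortas, to ask how loss of the beta catalytic subunit of calcineurin (Ppp3cb) alters the vascular response to 4 weeks of angiotensin II (AngII). WT and KO mice, control or AngII-treated, female or male, made up 8 groups of 3. Totals were 2510551 to 4205881 counts in WT control females, 3668011 to 3850424 in WT AngII females, 3462353 to 4724160 in WT control males and 3837176 to 4402370 in WT AngII males. In KO mice they were 1523328 to 2401264 in control females, 2535746 to 4888759 in AngII females, 4249753 to 4887383 in control males and 3271095 to 6352365 in AngII males. Smooth muscle myosin, Myh11, held 0.731% of all counts, the most of any protein-coding gene but the repeat-like Gm10800 (2.84%). The KO control female libraries stood apart. Olfactory and vomeronasal receptor genes, most of which are silent outside sensory tissue, held 1727 ± 584 CPM of protein-coding counts there (SD, n = 3), against 411 ± 201 in WT control females and 369 ± 49.7 in KO control males. Satellite-like sequences held 20.7 ± 13.4% of counts in that group, and 0.591% to 5.18% on average in the other 7 groups.

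Ppp3cb itself was lower in KO aortas over all mice, at -1.01 ± 0.16 log2 (SE; edgeR, adjusted p = 0.000177). The gene (ENSMUSG00000021816, chromosome 14, 20499364 to 20546573, minus strand, mm10) was at 41.9 ± 10.8 CPM in WT and 21.3 ± 6.11 CPM in KO (SD, n = 12 each). Counts at this gene in KO stood at 49.8% of WT. All 12 KO libraries lay below the WT median and 10 lay below every WT library (permutation test, p = 3.0e-05). Which part of the gene the targeted allele lacks is not stated in the labels, and gene-level counts cannot separate that part from the rest. The other calcineurin subunits were not called by edgeR in any comparison with all 24 libraries. Ppp3ca, the alpha catalytic subunit, differed between KO and WT by -0.15 ± 0.23 in control and 0.13 ± 0.23 in AngII mice. Ppp3cc differed by -0.17 ± 0.42 and 0.01 ± 0.41, and the regulatory subunit Ppp3r1 by -0.45 ± 0.46 and -0.30 ± 0.45. Without KO control female replicate 2 the Ppp3r1 value in controls was -1.95 and was called (adjusted p = 0.0326), and without replicates 1 and 3 of that group it was 0.19. Rcan1, an inhibitor of calcineurin that calcineurin-NFAT signalling itself induces, stood at 15.2 ± 5.97 CPM in WT controls and 40.8 ± 10.6 CPM in WT AngII mice (SD, n = 6). The difference of 1.44 ± 0.34 log2 missed the threshold (adjusted p = 0.07). It was called in 7 of 39 other settings, namely DESeq2, limma-voom with quality weights (lowest adjusted p, 7.52e-05), no count filter and only the groups compared. The rest were the fits without KO control female replicate 1, replicates 1 and 3 of that group, or WT AngII female replicate 1. In KO mice Rcan1 was at 7.60 ± 4.38 and 11.5 ± 3.94 CPM. Its relative Rcan2 differed by at most 0.31 ± 0.17 in the comparisons over both sexes.

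**Figure D1:**
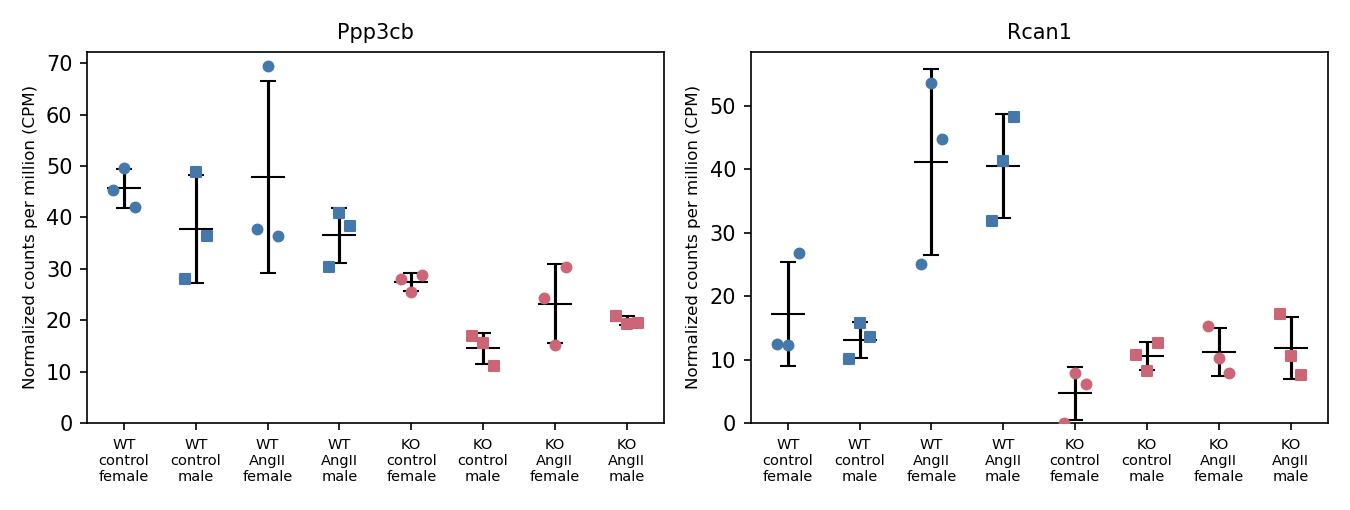
Ppp3cb and Rcan1 levels (CPM) in each library by genotype, treatment and sex, with the mean and SD of each group of 3 mice. Ppp3cb lies lower in KO (21.3 ± 6.11 CPM) than in WT (41.9 ± 10.8 CPM), and Rcan1 is highest in WT AngII mice (25.0 to 53.6 CPM).

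The first treatment comparison asked what AngII does to the WT aorta. Extracellular matrix genes rose together. All 36 tested members of the matrix list were higher after AngII, with a median of 1.00 log2 (camera, adjusted p = 1.01e-58, and 0.00481 with an estimated correlation). Of these, 14 were called over all genes and 29 when adjusted over the list alone. Among these matrix genes, Col1a1, the main chain of type I collagen (chromosome 11, 94936224 to 94953042), went from 646 ± 124 to 1800 ± 616 CPM (SD, n = 6). This is a rise of 1.46 ± 0.23 (adjusted p = 0.00235). Sparc, a collagen-binding glycoprotein (chromosome 11, 55394500 to 55423183), rose by 1.47 ± 0.22 (adjusted p = 0.0022). Periostin, Postn (chromosome 3, 54361109 to 54391037), rose by 1.44 ± 0.23 (adjusted p = 0.00235). In these 3 genes every AngII library lay above every control library. Acan, the cartilage proteoglycan aggrecan (chromosome 7, 79053483 to 79115099), rose by 2.48 ± 0.42 (adjusted p = 0.00643) from 10.4 ± 5.26 to 58.0 ± 37.8 CPM. Fibronectin, Fn1 (chromosome 1, 71585520 to 71653200), rose by 1.43 ± 0.31 (adjusted p = 0.0408). Fibroblast and adventitial markers rose in the same comparison (11 of 15 higher, median 0.32, adjusted p = 0.00589, and 0.416 with an estimated correlation).

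Genes that build and remodel matrix moved with it. All 14 tested genes of collagen processing were higher (median 0.66, 1 called, 12 adjusted over the list alone, adjusted p = 3.17e-15, and 0.00481 with an estimated correlation). Lox, which crosslinks collagen and elastin (chromosome 18, 52516067 to 52529867), rose by 1.25 ± 0.26 (adjusted p = 0.0303). Of the TGF-beta pathway and its responders 19 of 23 were higher (median 0.39, 2 called, 7 adjusted over the list alone, adjusted p = 5.2e-08, and 0.0258 with an estimated correlation). They include connective tissue growth factor, Ccn2 (chromosome 10, 24595442 to 24598683, 1.37 ± 0.26, adjusted p = 0.0121). Matrix proteases and their inhibitors rose (16 of 21 higher, median 0.48, adjusted p = 5.2e-08, and 0.0144 with an estimated correlation). Genes of the unfolded protein response rose too (18 of 19 higher, median 0.36, adjusted p = 2.59e-07, and 0.0244 with an estimated correlation). No chaperone among them was called over all genes, and Pdia4 was at 0.71 ± 0.20 and Pdia6 at 0.83 ± 0.24.

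Outside the lists, the largest rise in WT was that of Igfbp2, which binds insulin-like growth factors (chromosome 1, 72824503 to 72852474). It was at 3.48 ± 2.64 CPM in controls and 51.7 ± 32.6 CPM after AngII (SD, n = 6), a change of 3.73 ± 0.68 log2 (adjusted p = 0.0103). Mki67, a marker of dividing cells, rose by 2.36 ± 0.51 (adjusted p = 0.0353), the cytochrome b5 reductase Cyb5r3 by 1.63 ± 0.30 (adjusted p = 0.0112) and the tubulin Tubb4a by 1.47 ± 0.33 (adjusted p = 0.0454). Olfml2a fell by 1.13 ± 0.23 (adjusted p = 0.023), from 65.5 ± 15.1 to 29.9 ± 4.97 CPM, and every AngII library lay below every control library. The fall of Rab3c, a vesicle GTPase of neurons (-3.02 ± 0.63, adjusted p = 0.0265), rested on WT control male replicate 2, which held 72.8 CPM. Without it the value was -1.92 (adjusted p = 0.328). Macrophage markers were higher in 19 of 20 cases (median 0.69, adjusted p = 7.58e-08). Endothelial markers were lower in all but 2 of 15 (median -0.56, adjusted p = 8.28e-06). Neither of these held with an estimated correlation (adjusted p = 0.167 and 0.265), and no single marker of either list was called. Cd68 stood at 2.16 ± 0.51 and Emcn at -1.63 ± 0.46.

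In all, edgeR called 34 of 16316 genes in WT, 30 higher and 4 lower, where 1095 had an unadjusted p under 0.05. DESeq2 called 80 and limma-voom 329. With adipocyte and muscle covariates 7 were called, with the receptor share as a covariate 8, and in females only 0. In males only 24 were called, 22 higher and 2 lower, and 15 of them were among the 34. Leaving out 1 library at a time gave 4 to 93 calls. The count moved by more than 1.5 times without WT control female replicate 1 (6), 2 (16) or 3 (12), WT control male replicate 2 (5) or 3 (22), WT AngII female replicate 1 (93), 2 (11) or 3 (4), WT AngII male replicate 1 (17), 2 (22) or 3 (12), or KO control female replicate 1 (56). Sparc, Col1a1 and Postn were called in all 24 of these fits, Acan in 23, Igfbp2 in 22, Cyb5r3 in 20, Ccn2 in 18, Olfml2a and Rab3c in 16, Mki67 and Lox in 15, Fn1 in 8 and Tubb4a in 5.

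**Figure D2:**
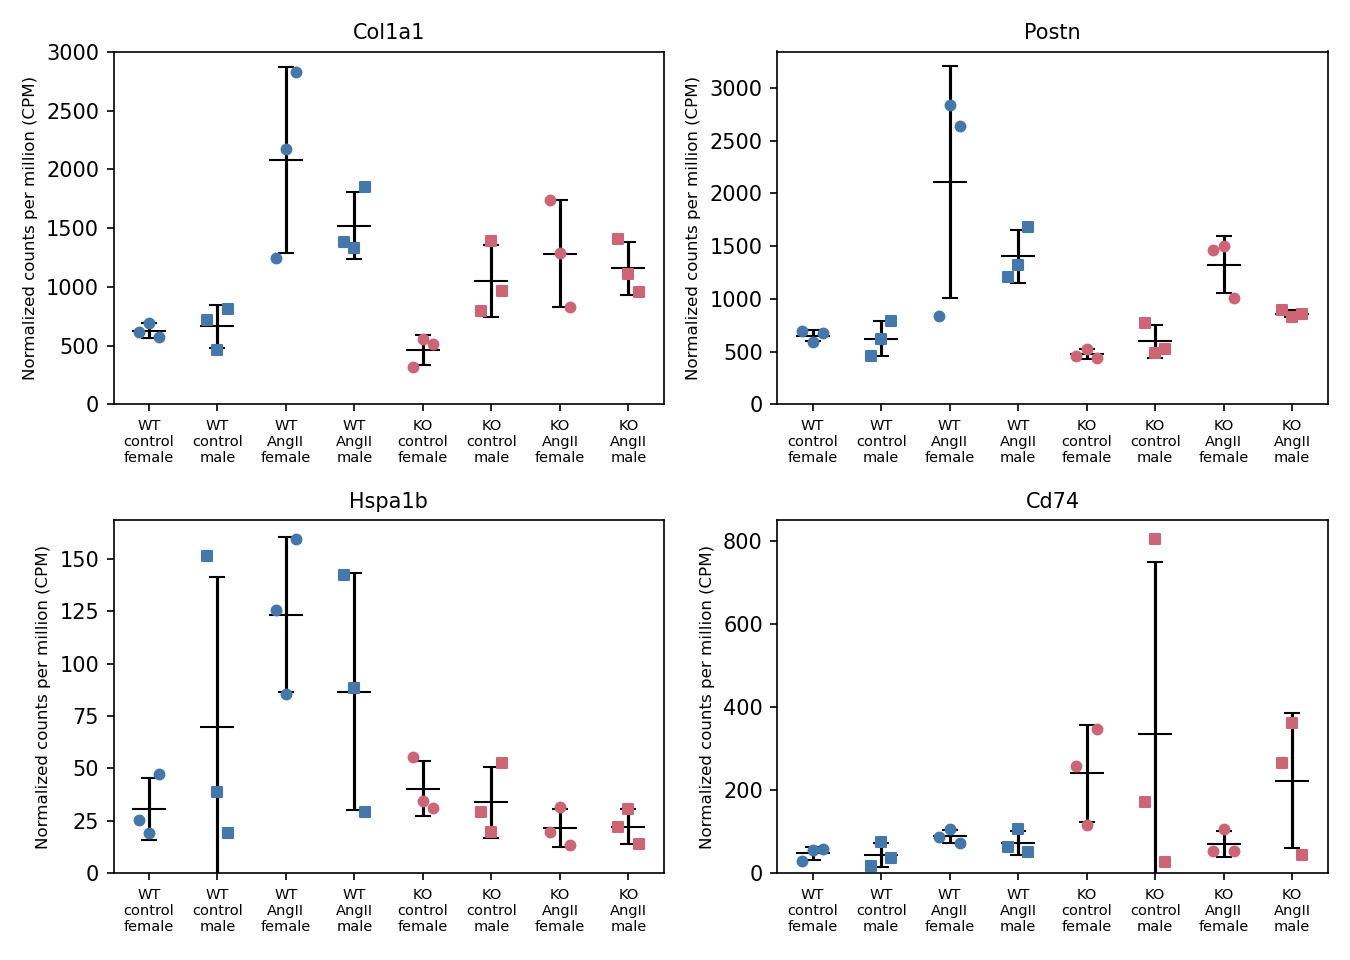
Levels (CPM) of Col1a1, Postn, Hspa1b and Cd74 in each library, by genotype, treatment and sex, with the mean and SD of each group of 3 mice. Col1a1 is at 1250 to 2830 CPM in WT AngII mice and at 460 to 813 CPM in WT controls; in KO mice it is at 829 to 1740 and at 318 to 1390 CPM.

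AngII in KO mice was compared to ask whether the same genes respond without Ppp3cb. The matrix list rose here too, with 30 of 36 members higher and a median of 0.57 (adjusted p = 1.58e-15), although not with an estimated correlation (adjusted p = 0.286). Postn stood at 1.00 ± 0.22, the collagen chain Col18a1 at 1.06 ± 0.24, Sparc at 0.86 ± 0.21 and matrix Gla protein, Mgp, at 1.11 ± 0.30, none of them called (adjusted p = 0.165, 0.165, 0.241 and 0.295). Collagen processing genes were higher in 13 of 14 cases (median 0.41, adjusted p = 0.000189, and 0.286 with an estimated correlation). TGF-beta genes were higher in 19 of 23 (median 0.26, adjusted p = 0.0035, and 0.426 with an estimated correlation). Neural and Schwann cell markers fell as a list (median -1.02, 4 of 14 higher, adjusted p = 0.000677, and 0.286 with an estimated correlation). Among neuronal genes, Dbh, the enzyme that makes noradrenaline, was at 18.3 ± 20.0 CPM in KO controls and 0.884 ± 1.77 CPM in KO AngII mice. The synaptic gene Snap25 was at 11.3 ± 8.52 and 0.141 ± 0.241 CPM (SD, n = 6). All 3 KO AngII males had 0 counts of either.

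No gene was called for AngII in KO by edgeR (smallest adjusted p = 0.106), and 1258 had an unadjusted p under 0.05; DESeq2 called 20 and limma-voom 0. Besides Snap25, the smallest p-values belonged to Igfbp2 (3.29 ± 0.70, adjusted p = 0.165), Lclat1 (1.13 ± 0.25), the potassium channel Kcna1 (-1.76 ± 0.39) and 1 gene with a systematic name. Left out one at a time, single libraries gave 0 to 100 calls, and 100 came without KO control female replicate 2. Receptor counts in KO control females were those given above, so the control side of this comparison carries those counts.

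Whether the AngII response differs between the genotypes was tested as the interaction, KO response minus WT response. All but 3 of the 36 matrix genes responded less in KO (median -0.41, adjusted p = 3.96e-08, and 0.358 with an estimated correlation). Col1a1 stood at -0.66 ± 0.32, Col3a1 at -0.67 ± 0.32 and Acan at -1.34 ± 0.57. Heat shock genes (median -0.44, 1 of 12 higher, adjusted p = 6.69e-05, and 0.342 with an estimated correlation) shifted the same way, with Hspa1b at -1.92 ± 0.54. So did macrophage markers (median -1.27, 2 of 20 higher, adjusted p = 3.34e-08, and 0.342 with an estimated correlation), with Cd68 at -2.24 ± 0.70. Rcan1 stood at -0.78 ± 0.51. Of the 33 lists 15 passed, 3 up and 12 down, and 0 passed with an estimated correlation. The KO control females that stand apart, with receptor genes at 1727 ± 584 CPM of protein-coding counts, enter this contrast. Without their replicates 1 and 3, 6 lists passed, in females only 5 and with adipocyte and muscle covariates 8. Cd68 was at 3.29 ± 2.52 CPM in WT controls, 13.3 ± 2.66 in WT AngII mice, 11.4 ± 8.55 in KO controls and 10.7 ± 5.55 in KO AngII mice (SD, n = 6).

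No gene was called for the interaction by edgeR, with every adjusted p at 1 and 657 unadjusted p-values under 0.05; DESeq2 and limma-voom called 0. In simulated data the same test called 49 of 100 genes with a 4-fold interaction and 5 of 100 with a 2-fold one. The smallest p-values were those of Asna1 (1.32 ± 0.35), Kdm8 and Tnfrsf13b, the last pair with 0 counts in all libraries of at least 1 group, and of 2 genes with systematic names. Without KO control female replicate 2 the count was 2. The list count fell to 9 without WT control male replicate 1 or KO AngII female replicate 3, to 8 without WT AngII female replicate 3 or KO control female replicate 1, and to 7 without KO AngII male replicate 3. Among the 30 genes that rose in WT, 29 were also higher after AngII in KO and all 30 by less, with a median of 1.32 in WT and 0.77 in KO. These genes were picked for their rise in WT, which favours a larger value there. Across all 16316 genes the 2 responses correlated weakly (r = 0.17, rho = 0.20, covariance 0.122; genes are not independent replicates). The value of r was 0.338 with a filter of 50 counts in 3 libraries, 0.0584 without a filter, -0.0172 with adipocyte and muscle covariates, 0.0214 in males only, 0.0845 in females only, 0.102 without WT control male replicate 2 and 0.0577 without KO control female replicates 1 and 3.

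**Figure D3:**
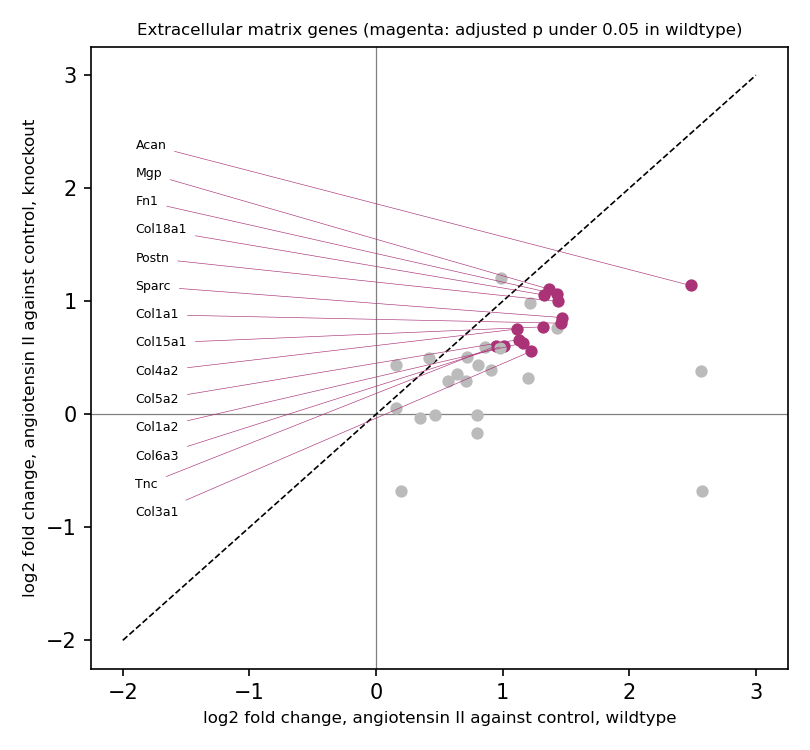
Log2 change after AngII in WT (horizontal) and in KO (vertical) for the 36 tested matrix genes, with the 14 genes called in WT labelled and a dashed line of equal change. The medians are 1.00 in WT and 0.57 in KO.

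KO was then compared with WT among control mice. Among the genes called higher in KO were 6 known from antigen presentation or the interferon response, the first of which was not a fixed list. Cd74, the invariant chain of class II presentation (chromosome 18, 60803848 to 60812652), rose by 2.64 ± 0.50 (adjusted p = 0.01) from 45.2 ± 21.2 to 288 ± 277 CPM (SD, n = 6). H2-Ab1, a class II chain (chromosome 17, 34257689 to 34269419), rose by 2.70 ± 0.58 (adjusted p = 0.0319). The interferon-induced GTPases Iigp1 (chromosome 18, 60376027 to 60392634) and Gbp4 (chromosome 5, 105115767 to 105139586) rose by 2.19 ± 0.37 (adjusted p = 0.00477) and 2.03 ± 0.43 (adjusted p = 0.0297). The class I genes H2-Q4 and H2-Q7 rose by 2.19 ± 0.47 (adjusted p = 0.0331) and 1.66 ± 0.30 (adjusted p = 0.00723). The interferon list was higher in 28 of 32 members (median 1.05, adjusted p = 9.47e-11, and 0.282 with an estimated correlation). The macrophage markers were higher in 20 of 20 (median 1.38, adjusted p = 1.28e-09, and 0.282 with an estimated correlation). In the same comparison the KO side includes the 3 control females with receptor genes at 1727 ± 584 CPM of protein-coding counts (WT control females, 411 ± 201). Iigp1 and H2-Q7 were called in all 24 fits that left out 1 library, Cd74 in 21, H2-Ab1 and Gbp4 in 16 and H2-Q4 in 15. Cd74 was not called without WT control female replicate 2, WT control male replicate 1 or KO control male replicate 2, which held 806 CPM.

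Further lists differed between KO and WT controls, a comparison in which satellite-like sequences made up 20.7 ± 13.4% of counts in KO females and 4.60 ± 3.41% in WT females. Inflammatory cytokines were higher in 21 of 24 (median 1.09, adjusted p = 0.000325, and 0.395 with an estimated correlation), with the adhesion molecule Vcam1 at 1.11 ± 0.32. Skeletal muscle markers were higher in 11 of 14 (median 0.75, adjusted p = 0.00823, and 0.282 with an estimated correlation). Genes of fatty acid metabolism were lower in all but 1 of 23 (median -0.54, adjusted p = 2.16e-06), with fatty acid synthase, Fasn, at -0.96 ± 0.37. Those of oxidative phosphorylation were lower too (all but 1 of 23, median -0.39, adjusted p = 8.8e-06). Markers of adipocytes (median -0.43, adjusted p = 0.000325), brown adipocytes (median -0.70, adjusted p = 0.00823) and contractile smooth muscle (median -0.30, adjusted p = 0.00318) were lower as well. Among them Lipe stood at -1.08 ± 0.38, Cidea at -0.78 ± 0.36 and Myl9 at -0.46 ± 0.20. With an estimated correlation the adjusted p was 0.424 for brown adipocytes and 0.395 for the other 4 of these lists.

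By edgeR 36 genes were called between KO and WT controls, 33 higher and 3 lower, 27 of them with systematic names; DESeq2 called 178 and limma-voom 43. Beside Ppp3cb (-1.06 ± 0.22, adjusted p = 0.0297), Plekhh2 was lower (-0.97 ± 0.21, adjusted p = 0.0331) at 23.3 ± 7.58 against 44.5 ± 7.34 CPM. Kdm8 was called lower (adjusted p = 0.0342) because it had 0 counts in all 3 KO control females, and in males alone the value was -0.30. Each of 4 other fits called 0 genes: males only, adipocyte and muscle covariates, the receptor share as a covariate, and the fit without KO control female replicates 1 and 3, where receptor genes held 2125 and 2000 CPM of protein-coding counts. Leaving out 1 library moved the count to 9 (WT control female replicate 2), 19 (WT control male replicate 1), 57 (WT control male replicate 2), 357 (KO control female replicate 2) or 22 (KO control male replicate 1). The 357 were 108 higher and 249 lower, so the balance of direction turned.

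KO was also compared with WT among AngII-treated mice. Receptor genes were higher in KO here too, at 762 ± 341 against 290 ± 93.6 CPM of protein-coding counts in females and 442 ± 163 against 160 ± 55.8 in males (SD, n = 3). Heat shock genes were lower in KO in 12 of 12 cases (median -0.68, 3 called, 7 adjusted over the list alone, adjusted p = 1.41e-13, and 0.0213 with an estimated correlation). Hspa1b, an inducible Hsp70 (chromosome 17, 34956436 to 34959238), was at 105 ± 47.3 CPM in WT and 21.8 ± 7.85 CPM in KO (SD, n = 6), -2.24 ± 0.39 (adjusted p = 0.0036). Its near-identical neighbour Hspa1a, which shares reads with it, stood at -1.92 ± 0.40 (adjusted p = 0.0174), and the co-chaperone Hsph1 at -1.26 ± 0.25 (adjusted p = 0.0115). Rcan1 (chromosome 16, 92391953 to 92470867) was lower, at -1.83 ± 0.35 (adjusted p = 0.00744). All 6 KO libraries (7.64 to 17.2 CPM) lay below all 6 WT libraries (25.0 to 53.6 CPM).

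Lox, Ccn2 and Tgfb3 were lower in AngII-treated KO mice than in AngII-treated WT mice. Lox differed by -1.15 ± 0.26 (adjusted p = 0.0374), Ccn2 by -1.14 ± 0.26 (adjusted p = 0.0329) and the growth factor Tgfb3 by -0.79 ± 0.18 (adjusted p = 0.0368). The collagen processing list (3 of 14 higher, median -0.34, adjusted p = 8.27e-06), the TGF-beta list (6 of 23 higher, median -0.26, adjusted p = 2.92e-05) and the matrix list (6 of 36 higher, median -0.37, adjusted p = 2.94e-07) went the same way. With an estimated correlation their adjusted p was 0.187, 0.187 and 0.434. Immediate early genes were lower (median -0.40, adjusted p = 0.00026, and 0.434 with an estimated correlation). Nr4a3 stood at -1.61 ± 0.51 and Atf3 at -2.25 ± 0.73. Higher in KO were the sarcomere protein Tcap (1.71 ± 0.31, adjusted p = 0.00425, 30.8 ± 18 CPM in WT and 92.2 ± 37.5 CPM in KO) and the clock output factor Hlf (1.46 ± 0.30, adjusted p = 0.0143). So were the adhesion receptor Adgrv1 (2.81 ± 0.60, adjusted p = 0.022) and the ephrin receptor Epha5 (2.61 ± 0.59, adjusted p = 0.0329). The interferon list was higher in 31 of 32 members (median 0.63, adjusted p = 4.38e-06, and 0.378 with an estimated correlation), with no member called.

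In this comparison edgeR called 58 genes, 50 higher and 8 lower in KO, 45 of them with systematic names; DESeq2 called 146 and limma-voom 200. With the receptor share as a covariate 2 remained, in males only 0 were called and in females only 1, while the fit without KO control female replicates 1 and 3 called 62. The count was 31 to 65 with 1 library left out and moved by more than 1.5 times without WT AngII male replicate 1 (31) or 2 (33). Hspa1b, Rcan1 and Tcap were called in all 24 of these fits, Hsph1 in 23, Hlf in 20, Adgrv1 in 18, Hspa1a in 17, Epha5, Ccn2 and Lox in 15, and Tgfb3 and Ppp3cb (-0.96 ± 0.22, adjusted p = 0.0394) in 14.

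Most genes with systematic names that were higher in KO came from 1 repeated gene family. At chromosome 14, 3 to 8 Mb, 157 genes were tested, and 154 of them were higher in KO in control mice (median 2.34) and 153 in AngII mice (median 2.79). Of these, 25 were called in control mice, 42 in AngII mice, 20 in both and 47 in either. The window was chosen after the calls were seen, and reads that match several copies count at each, so these are not independent genes. Summed over the family, KO control females stood at 3610 ± 1200 CPM against 489 ± 140 CPM in WT (SD, n = 3), while KO control males stood at 668 ± 53.2 against 506 ± 128 CPM. Closer to Ppp3cb, between 19532896 and 19602581 on the same chromosome, Gm5458 was called higher in control KO mice (4.03 ± 0.76, adjusted p = 0.01), and Gm2244 (3.37 ± 0.62, adjusted p = 0.0047) and Gm2237 (2.32 ± 0.49, adjusted p = 0.0177) in AngII-treated ones.

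**Figure D4:**
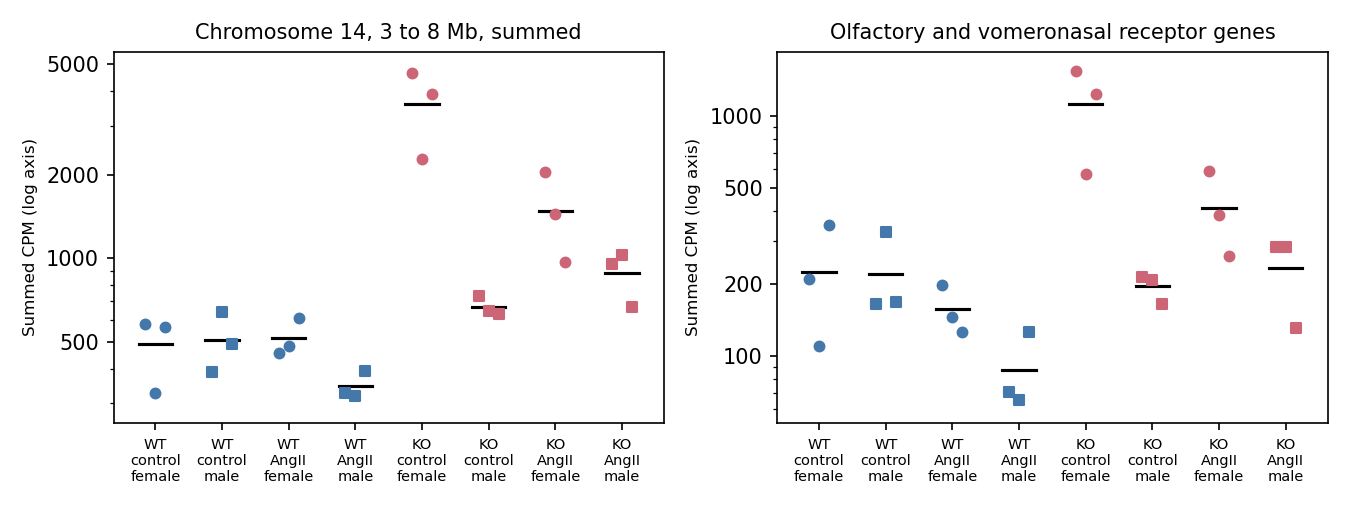
Summed level (CPM, log axis) of the 157 tested genes at chromosome 14, 3 to 8 Mb, in each library, beside the counts on olfactory and vomeronasal receptor genes; lines mark the mean of each group of 3 mice. Both are highest in KO control females, at 3610 ± 1200 CPM for the family.

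The response to AngII was also compared within each sex, 3 mice against 3. In WT females matrix genes led the list of smallest p-values, with Col1a1 at 1.73 ± 0.32, Sparc at 1.64 ± 0.31 and Postn at 1.69 ± 0.32 (adjusted p = 0.0545 each), followed by Tubb4a (2.42 ± 0.49) and Ccn2 (1.78 ± 0.37). The matrix list (33 of 36 higher, median 0.99) and the collagen processing list (14 of 14 higher, median 0.56) passed in WT females with an estimated correlation too (adjusted p = 0.0142 each), and in the fit on females alone their adjusted p was 0.0834 and 0.0746. In WT males 35 of 36 matrix genes (median 0.97, adjusted p = 2.51e-31, and 0.0663 with an estimated correlation) and 14 of 14 collagen processing genes (median 0.56, adjusted p = 6.7e-07, and 0.0834 with an estimated correlation) were higher. In the fit on males alone the matrix, unfolded protein response and TGF-beta lists passed with an estimated correlation (adjusted p = 0.0159, 0.0308 and 0.0423). In WT males the smallest p-values included Rab3c (-4.56 ± 0.95), H2-Q10 (4.52 ± 0.96), the proteoglycan Sdc4 (1.09 ± 0.25) and Col18a1 (1.45 ± 0.34), at an adjusted p of 0.272. In KO females they were those of Dgcr2 (2.66 ± 0.52), Cd59a (2.15 ± 0.42), Col18a1 (1.74 ± 0.34), Akirin1 (2.77 ± 0.55) and Hist1h4n, which had 0 counts in KO control females, at an adjusted p of 0.0521. In KO males neural and Schwann markers fell (median -1.93, 1 of 14 higher, adjusted p = 6.63e-11, and 0.0205 with an estimated correlation, but 0.22 in the fit on males alone). Snap25, Dbh, Pask, Ano4 (4.52 ± 1.01) and Kcna1 (-2.47 ± 0.56) had the smallest gene p-values (adjusted p = 0.46). The first 3 of them had 0 counts in KO AngII males.

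No gene was called by edgeR in any single-sex comparison within the model of all 24 libraries. There, unadjusted p-values under 0.05 numbered 509 in WT females, 1082 in WT males, 1977 in KO females and 498 in KO males. The edgeR fit on males alone called 24 genes for AngII in WT (22 higher, 2 lower) and 1 in KO, and the fit on females alone 0 in either. DESeq2 called 25, 20, 118 and 1 gene in these groups, and limma-voom called 269 in WT females and 0 in the other groups. With 3 mice against 3, the simulated data gave 40 of 100 genes changed 4-fold in WT females and 5 of 100 changed 2-fold. The sex difference of the AngII response was itself tested and gave 0 calls in WT (515 unadjusted, DESeq2 3, limma-voom 0), 0 in KO (1237, DESeq2 16, limma-voom 6) and 0 for the 3-way interaction with genotype (1068, DESeq2 7, limma-voom 3). The smallest adjusted p was 0.161, with H2-Q10 at 6.42 ± 1.23 and Fst at -3.45 ± 0.75 in WT, 0.0907 with Ano4 at 6.47 ± 1.19 and Tuba1a at -1.56 ± 0.35 in KO. It was 0.0992 with Ano4 at 8.38 ± 1.54 in the 3-way test, where genes with systematic names held the other places. Between WT control males and females 0 genes were called (605 unadjusted, DESeq2 2, limma-voom 0), with H2-Q10 at -5.43 ± 0.97 (adjusted p = 0.0619), complement C7 at 1.84 ± 0.42, Id4 at 2.36 ± 0.57 and Uqcrb at -1.23 ± 0.30. Across genes the AngII response of females and males correlated at r = 0.12 in WT and 0.00 in KO. The WT value was 0.0109 without WT control female replicate 3, 0.0688 without WT control female replicate 1, 0.0642 without WT control male replicate 3, 0.174 without WT AngII female replicate 1, 0.0465 without a count filter and 0.214 with the receptor share as a covariate. The KO value was -0.0596 to 0.0811 with 1 library left out. With 1 library left out the counts reached 27 in WT females (without WT AngII female replicate 1), 5 in WT males (without WT control male replicate 1) and, without KO control female replicate 2, 592 in KO females and 75 for the sex difference in KO.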

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

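The comparison of background counts with the chromosome 14 family, the adipocyte and muscle, time-of-day and fixed-difference tests, the receptor share used as a covariate, and the errors from the fits with covariates were chosen after the results were seen; the strain segment, macrophage and split tests were written before.

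The interaction test set 15 lists apart, as a difference between the genotypes in their response to AngII (median of KO response minus WT response, adjusted p at the preset correlation, then with an estimated correlation). Lower in KO were extracellular matrix (-0.41, adjusted p = 3.96e-08, estimated 0.358), macrophage markers (-1.27, adjusted p = 3.34e-08, estimated 0.342), heat shock (-0.44, adjusted p = 6.69e-05, estimated 0.342), matrix proteases (-0.28, adjusted p = 0.0126, estimated 0.358), cardiac muscle markers (-0.92, adjusted p = 0.0136, estimated 0.332) and the unfolded protein response (-0.21, adjusted p = 0.0136, estimated 0.358). So were collagen processing (-0.25, adjusted p = 0.0182, estimated 0.473), inflammatory cytokines (-0.49, adjusted p = 0.0443, estimated 0.604), interferon response (-0.39, adjusted p = 0.0443, estimated 0.611), neural and Schwann markers (-0.62, adjusted p = 0.0443, estimated 0.473), cell cycle (-0.22, adjusted p = 0.0447, estimated 0.473) and skeletal muscle markers (-0.56, adjusted p = 0.0447, estimated 0.358). Higher were adipocyte markers (0.26, adjusted p = 0.00661, estimated 0.604), fatty acid metabolism (0.26, adjusted p = 0.0126, estimated 0.611) and oxidative phosphorylation (0.24, adjusted p = 0.0182, estimated 0.611). Outside the comparisons, receptor genes mostly silent outside sensory tissue held 1727 CPM of protein-coding counts in KO control females, against 411 in WT control females.

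Genes of the chromosome 14 family were higher in KO, by 1.52 ± 0.31 log2 for their sum over all strata of sex and treatment (SE, exact p = 2.5e-05), and counts on mostly silent receptor genes, taken here as a measure of genomic DNA background without a test of their origin, were higher by 1.24 ± 0.39 (exact p = 0.000525). Within groups family and receptor counts went together (r = 0.85, rho = 0.80, n = 24, permutation p = 1e-05, the smallest the permutations allow, and 2e-05). Adjusted over 2 relations these were 2e-05 and 4e-05, and r was 0.78 without the 2 farthest libraries. Both counts were scaled by the same library sizes, which alone can make them go together. Deviations from group means were permuted as if independent, so these p-values may be too small. The median single gene of the family differed by more, 2.34 in control and 2.79 in AngII mice. That median was not set against the receptors, although the prediction for control males named it. For the family's sum, receptor background goes with most of the difference. Whether it is the whole of it stays open: the family exceeded the receptors by 0.53 ± 0.41 in control males, and over all strata by 0.33 ± 0.14 with receptors per protein-coding count (exact p = 0.0384, tried first) and by 0.28 ± 0.14 with receptors as CPM (exact p = 0.0548), a second scaling and a rule that both must pass that were settled after the first value was seen. A segment of the donor strain around Ppp3cb stays open too. For genotype over all mice, 16.2% of 197 genes within 20 Mb had an unadjusted p under 0.05, against 12.1% elsewhere (odds ratio 1.4, Fisher p = 0.0991). The chromosome 14 family was left out of this share, while Gm5458, Gm2244 and Gm2237 were not. An effect of the genotype itself was not tested apart from these.

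A set of 7 genes (Hspa1b, Hspa1a, Rcan1, Hsph1, Lox, Ccn2 and Tgfb3) was lower in AngII-treated KO mice, with a median of -1.25; they were picked because they were called there, and Hspa1a and Hspa1b share reads. For these 7 genes, differences in adipocyte and muscle content are argued against by a median of -1.28 with both covariates (4 of 7 still called). For genomic DNA background the median was -1.35 with the receptor share as covariate, which does not decide the question. There 0 of 7 were called, as the median SE of a gene went from 0.26 to 0.42 and the median difference did not shrink. Receptor counts themselves were higher in KO under AngII, by 1.39 log2 in males and 1.34 in females, so this covariate overlaps with genotype. Reads added by background would also raise counts in KO, so removing them could hardly bring these lower values toward 0. No conclusion on background is drawn from this fit. In linear models with these covariates the SE of the genes' mean log2 CPM was 0.25 and 0.35. A GC correction, which was weighed at first and dropped for the time-of-day test, left -1.29 and all 7 called. Collection at another time of day cannot be told apart from genotype: clock genes of the Arntl arm and the output arm differed between KO and WT by 2.04 ± 0.47 under AngII (exact p = 0.01) and by 1.63 in controls (exact p = 0.015), while within groups clock and 7-gene levels had r = -0.25 (permutation p = 0.23), rho = -0.26 (p = 0.22) and r = -0.09 without the 2 farthest libraries. An effect of calcineurin loss on these genes therefore stays a hypothesis beside time of day, with genomic DNA background undecided.

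Antigen presentation and interferon genes (H2-Ab1, Cd74, Iigp1, H2-Q4, Gbp4 and H2-Q7) were higher in control KO mice, with a median of 2.19. A fixed difference between the mouse lines stays open, as the median under AngII was 0.93 ± 0.43, near the 1.10 set as its bound, and the 6 interactions were all negative, with an unadjusted p of 0.00557 for Cd74, 0.0231 for H2-Ab1, 0.0434 for H2-Q4, 0.0483 for Iigp1 and 0.147 for the other 2 (adjusted p = 1 each), in genes picked for a high value in controls. For more macrophages or other leukocytes, the prediction written before was a positive macrophage list median over both sexes and in each sex. It was met, with medians of 1.67 in males and 0.75 in females. This cause stays open all the same, as the camera adjusted p was 0.571 and 0.558 with an estimated correlation. Genomic DNA background stays open by the covariate test, at a median of 1.52 ± 0.58 with the receptor share as covariate and 0 of 6 genes called. Reads added by it are argued against for these 6 genes, if background falls on them as on receptor genes. In KO control females 1321 receptor genes together held 1110 CPM. H2-Q7, with the smallest log2 rise of the 6, went from 20.7 to 69 CPM over both sexes. In control males receptors differed by -0.11 ± 0.35 log2 by genotype. All 6 genes stayed higher in KO in every setting (lowest 0.826, Gbp4), although males only called 0 genes. The errors 0.43 and 0.58 are those of the 6 genes' mean log2 CPM, over libraries and in a linear model with the covariate. For these bounds the spread was changed from that over genes to that over libraries after the outcomes were seen, which turned 2 outcomes of this pattern from decided to open, and an effect of genotype on inflammation was not tested apart from them.

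Splits of the same samples, the real one counted among them, were run through the whole test. For AngII in WT 1 of 100 splits gave as many calls as the 34 seen (highest other 30) and 2 of 100 splits as many lists as the 17 seen (highest other 18). For KO against WT in controls 3 of 100 splits gave as many as the 36 seen (highest other 97), and under AngII 1 of 100 splits as many as the 58 seen (highest other 7); the 15 interaction lists were reached in 4 of 100 splits (highest other 17). All but the last of these results argue against an arbitrary grouping, without adjustment over the split tests. They do not tell genotype or treatment from other differences between the groups. The interaction splits exchanged genotype labels within sex and treatment, which removes every genotype difference. They therefore cannot single out the interaction, and no conclusion on it is drawn. For the other list counts an arbitrary grouping stays open. As many lists came in 20 of 100 splits for AngII in KO (8 seen, highest other 14), 16 of 100 splits for KO against WT in controls (11 seen, highest other 17) and 31 of 100 splits under AngII (11 seen, highest other 18). Where 0 genes were called, every split gives as many (100 of 100 splits), so the count says nothing, and the highest others were 21 for AngII in KO, 7 for the interaction, 14 and 938 for the sex difference in WT and KO, and 3 for the 3-way interaction. What the libraries grouped by the split with 938 calls have in common was not tested. For 3 mice against 3, only 10 splits exist, too few to tell: 0 calls were seen, and the highest others were 0 in WT females, 0 in WT males, 25 in KO females, 3 in KO males and 1 between WT control males and females.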

How the results depend on the processing

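The protein-coding, receptor-share, GC, males-only and females-only fits and the fit without KO control female libraries 1 and 3 were chosen after the data were seen. No named call changed sign. Calls for KO against WT in controls turned from 33 higher and 3 lower to 108 higher and 249 lower without KO control female replicate 2, and the agreement of WT and KO changed sign with adipocyte and muscle covariates. Results for single genes under all alternatives were sorted by call, not by size of change. In 2090 the gene was called in both fits, or in neither with a value within its SE. In 390 the call was lost, in 8 it was gained, and in 39 an uncalled value moved by more than its SE. Values of called genes could still shift, as for Gbp4 in control mice (2.027 in the main fit, 0.826 to 3.144 in the others). Depth on messenger RNA limits calls of genes with few counts. The cause of the changes below was not tested, except where fewer genes or libraries were fitted.

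Counts of calls changed as follows. Library totals alone gave 12 for AngII in WT and 1 in KO. Without a count filter there were 134 calls for AngII in WT, 85 in KO, 12 for the interaction, 260 for KO against WT in controls and 182 under AngII, then 41 in WT females, 93 in WT males, 230 in KO females, 9 in KO males, 9 for the sex difference in WT, 33 in KO, 35 for the 3-way interaction and 35 between the sexes, with 14 lists in KO and an agreement of WT and KO of 0.0584. With DESeq2 the same comparisons gave 80, 20, 0, 178 and 146, then 25, 20, 118, 1, 3, 16, 7 and 2. With limma-voom there were 329 for AngII in WT, 200 for KO against WT under AngII, 269 in WT females, 6 for the sex difference in KO and 3 for the 3-way interaction. RLE factors gave 3 in WT females, protein-coding genes alone 3 in WT females and 17 in KO females, and the GC correction 3 in WT females. A filter of 50 counts in 3 libraries gave 22 for KO against WT in controls, 7 lists for the interaction, 7 for KO against WT in controls and an agreement of 0.338.

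With adipocyte and muscle covariates there were 7 calls for AngII in WT, 0 for KO against WT in controls, 8 lists for the interaction, 6 for KO against WT in controls and an agreement of -0.0172. The receptor share as a covariate gave 8 for AngII in WT, 0 and 2 for KO against WT in controls and under AngII, 3 lists in controls, and Ppp3cb at -1.05. Without KO control female libraries 1 and 3 there were 60 for AngII in WT, 0 for KO against WT in controls, 4 in WT females, 4 in KO females, 3 lists in KO, 6 for the interaction, 6 for KO against WT in controls and an agreement of 0.0577. Females only gave 0 for AngII in WT, 98 and 1 for KO against WT in controls and under AngII, and 5 interaction lists. Males only gave 24 calls for AngII in WT, 1 in KO, and 0 and 0 for KO against WT. They also gave 4 lists in KO, 7 for KO against WT under AngII and an agreement of 0.0214. Fits on only the groups compared gave 1 for AngII in KO, 22 for KO against WT in controls, 1 in WT males and 3 in KO males. The replicate number as a block gave 24 for AngII in WT, 0 in KO, 0 for the interaction, 30 and 52 for KO against WT, and 1 between the sexes. Libraries of different groups with the same number had a mean correlation of 0.00413, against -0.00179 for different numbers, and 12 of 24 were closest to a library with their own number. With an estimated correlation 5, 0, 0, 0 and 1 lists passed in the 5 comparisons over both sexes.

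Leaving out 1 library at a time gave 4 to 93 calls for AngII in WT, 0 to 100 in KO, 0 to 2 for the interaction, 9 to 357 for KO against WT in controls and 31 to 65 under AngII. It gave 0 to 27 in WT females, 0 to 5 in WT males, 0 to 592 in KO females, 0 to 0 in KO males, 0 to 1 and 0 to 75 for the sex difference in WT and KO, 0 to 2 for the 3-way interaction and 0 to 1 between the sexes. Lists ranged over 13 to 18, 6 to 12, 7 to 17, 9 to 14 and 9 to 15, agreement over 0.102 to 0.199 between WT and KO, 0.0109 to 0.174 between the sexes in WT and -0.0596 to 0.0811 in KO, and Ppp3cb over -1.09 to -0.914.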

Other observations

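No test in this part was chosen after the data were seen. Clock genes were set apart by genotype under AngII (13 of 19 higher in KO, median 0.36, 1 called, camera adjusted p = 0.00234, and 0.3 with an estimated correlation). Arntl, which drives the clock, stood at -2.04 ± 0.49 (adjusted p = 0.0622), and the output genes Tef, Per3 and Bhlhe41 stood at 0.82 ± 0.21, 0.89 ± 0.23 and 1.09 ± 0.27, beside Hlf, which rose. Lymphocyte markers were higher in KO in 9 of 10 cases in controls (median 1.35, adjusted p = 0.0127, and 0.395 with an estimated correlation) and 10 of 10 under AngII (median 1.07, adjusted p = 0.0233, and 0.462 with an estimated correlation), where the immunoglobulin chain Ighm stood at 2.38 ± 0.72. The calcineurin list, which contains Ppp3cb, was lower in KO in controls (median -0.16, adjusted p = 0.0144, and 0.395 with an estimated correlation) and under AngII (median -0.06, adjusted p = 0.0438, and 0.436 with an estimated correlation). Unfolded protein response genes (0 of 19 higher, median -0.12, adjusted p = 0.0102, and 0.378 with an estimated correlation) and brown adipocyte markers (1 of 13 higher, median -0.60, adjusted p = 0.025, and 0.657 with an estimated correlation) were lower in KO under AngII.

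After AngII in WT, further lists passed at the preset correlation only: heat shock (11 of 12 higher, median 0.36, adjusted p = 3.04e-05), calcification (10 of 15, median 0.48, 0.00255), NADPH oxidase and antioxidants (16 of 20, median 0.19, 0.00589), fibroblasts (11 of 15, median 0.32, 0.00589), cell cycle (20 of 30, median 0.47, 0.00877), immediate early genes (19 of 30, median 0.21, 0.0349) and blood (5 of 6, median 0.96, 0.0349) rose. Fatty acid metabolism (3 of 23 higher, median -0.21, 0.00589), adipocytes (6 of 20, median -0.16, 0.00592) and oxidative phosphorylation (6 of 23, median -0.17, 0.0349) fell. With an estimated correlation the adjusted p of these lists was, in the same order, 0.115, 0.0833, 0.27, 0.416, 0.27, 0.551, 0.27, 0.551, 0.548 and 0.573. Sod3, an extracellular superoxide dismutase, stood at 1.09 ± 0.26 and the platelet factor Ppbp at 3.78 ± 1.13. The list of ribosomal, mitochondrial and unprocessed RNA held no tested gene of chromosome MT, where all counts were 0. Lists that did not pass in WT were calcineurin (adjusted p = 0.195), clock (0.785), inflammatory cytokines (0.271), interferon response (0.878), the renin-angiotensin-aldosterone system (0.72; median 0.04, mean -0.03), contractile smooth muscle (0.52), vascular tone (0.178), brown adipocytes (0.348), cardiac muscle (0.151), lymphocytes (0.256), mesothelium and epithelium (0.151), neural and Schwann cells (0.151), neutrophils and mast cells (0.878; median -0.08, mean 0.11), ribosomal, mitochondrial and unprocessed RNA (0.113), skeletal muscle (0.692) and thymocytes (0.72).

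After AngII in KO, antioxidant genes rose (15 of 20 higher, median 0.23, adjusted p = 0.0134, and 0.475 with an estimated correlation). The list of ribosomal, mitochondrial and unprocessed RNA rose too, with no gene of chromosome MT among its tested members (6 of 6 higher, median 0.49, adjusted p = 0.0226, and 0.509 with an estimated correlation). Interferon genes (9 of 32 higher, median -0.37, adjusted p = 0.0134, and 0.54 with an estimated correlation) and endothelial markers (2 of 15 higher, median -0.37, adjusted p = 0.0068, and 0.517 with an estimated correlation) fell. In this comparison Sod3 stood at 1.04 ± 0.26, Ifit1 at -1.29 ± 0.49 and the endothelial receptor Tie1 at -0.60 ± 0.29.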
